A study of Nothobranchius furzeri with 10 samples.

How the data were processed

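Liver RNA of the turquoise killifish, *Nothobranchius furzeri*, a short-lived fish used to study ageing, was sequenced from 10 male samples of the strain MZM-0410p at 27 weeks of age. Per the labels, 5 samples came from fish given DMSO, the solvent control, and 5 from fish given rotenone at 15 pM. Libraries were made from total RNA with a TruSeq RNA kit (version 2), per the labels' protocols. The submitters' processing notes name bcl2fastq 1.8.4, STAR 2.4.1d and featureCounts 1.4.6-p4, without parameters. The genome build, the annotation and the strand setting are not given in the sources used here, so overlapping genes, antisense genes and near-identical copies could share reads.

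The authors deposited a table of read counts per gene for 26739 genes, whole numbers with a different total in each library, and this unit was read from the values. The authors also deposited a table of RPKM (read counts scaled by gene length and library total) for the same genes and libraries, named so by the table itself. Dividing the counts by the deposited RPKM should give 1 gene length in every library. Over the 7713 genes with at least 200 counts in every library, the implied length had a median coefficient of variation of 0.153 between libraries when each library's own total was used. With the column totals taken in a cycle down the genes, the median was 3.49e-05 and the largest value 0.000809. Only 10.0% of the deposited RPKM values were therefore on the scale of their own library's total, and single values were shifted by a factor of 0.696 to 1.44. The deposited RPKM were used only as an alternative, beside RPKM recomputed from the counts with each library's own total. Gene lengths were taken from the same calculation for the 22405 genes with a count, and were not checked against an annotation.

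Totals per library ran from 29162530 to 41902929 counts. Group membership came from the labels alone. The replicate numbers only name the libraries and pair nothing, and no batch is given in the labels. The labels number the samples but do not say in words that each came from a separate fish, so p-values measure the spread between these samples, which may be partly technical. The 20 pairs of libraries within a group differed by more than counting error (chi-square per degree of freedom from 74.5 to 439), so no pair looked like copies of a single library. This check covers counting error only and does not show that the libraries came from separate fish. All 10 were used as the replicates the labels list.

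Counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, TMM normalization, filterByExpr by group, no covariates), and p-values were adjusted by the Benjamini-Hochberg method. A gene is called here when its adjusted p lay under 0.05. The filter kept 16922 genes, which held 99.9% of all counts. Standard errors of log2 fold changes are approximate, from the fold change and its F statistic. CPM (the usual library-scaled count unit) includes the TMM factor, and log2 CPM used a prior count of 2. The share of expression variance lying between the groups was tested one-sided with an exact permutation test, and differences in spread and in library measures with exact permutation tests, two-sided, over all 252 assignments of the labels. These tests, their alternatives and the rule for named genes were fixed before the data were examined.

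The files give gene IDs and do not pair them with gene names. None of the 26739 IDs (0) matched the RefSeq gene table at hand, of assembly NfurGRZ-RIMD1. For this reason the test of 52 gene lists of pathways and cell types, planned with limma, could not be run, and the share of counts in mitochondrially encoded genes is not analysed here. The planned rule named called genes that had a gene symbol and a mean of at least 1 CPM in a group, by size and by lowest p, together with list members. With no symbols, the symbol condition was dropped after the data were examined, and the genes named are the pair of lowest p in each direction.

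Alternatives changed 1 choice each, except that DESeq2 also brought its own scaling and gene filter, and limma on RPKM its own unit and scaling: DESeq2 size factors, upper-quartile scaling or library size only; no count filter or a mean count of at least 10; DESeq2 1.42.0, limma 3.58.1 (voom, with and without sample quality weights, and limma-trend on log2 RPKM with a pseudocount of 1 or 0.1) or robust edgeR; an adjusted p threshold of 0.1; a fold change of at least 1.5; and each library left out in turn. Adjusted p-values that DESeq2 gives as missing (9711 genes) stayed missing. Added after the data were examined were RPKM with own totals, libraries thinned to the smallest total, removal of a length trend, covariates for the block of genes described in the results and for the share of the 50 most abundant genes, and DESeq2 without DMSO replicate 2. For the share of variance and the spread, a setting with only the genes outside the block and its correlates was also added then.

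The tests were tested on simulated data: counts drawn for the 16922 genes of the rotenone against DMSO comparison, with 200 genes changed. edgeR recovered 0% of genes changed 1.5-fold, 26% of those changed 2-fold, 88% at 4-fold and 96% at 8-fold, and 3 of its 108 calls were false. DESeq2 recovered 6%, 56%, 94% and 96% at the same sizes, and 24 of its 150 calls were false. Each gene was drawn independently and in a single draw. Variation shared between genes was therefore absent, and the rates of false calls may not carry over to these libraries.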

Results

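Rotenone blocks complex I of the mitochondrial respiratory chain, and DMSO is the solvent it is commonly given in. Gene expression in the liver was measured by RNA sequencing in 5 DMSO and 5 rotenone libraries. The DMSO libraries held 41902929, 32775234, 35024646, 37760406 and 36076210 counts, and the rotenone libraries 30254604, 32155568, 39514232, 29162530 and 36205789 counts. Counts were found for 22405 of the 26739 genes in the table, and 4334 had none. The design holds a single comparison, of rotenone with DMSO, which asks how the liver transcriptome differed between treated and control samples.

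Expression over all tested genes differed between rotenone and DMSO livers, with wide variation within each group. Of the variance in log2 CPM over 16922 genes, 21.8% lay between the groups, against a mean of 11.1% over all splits of the libraries (permutation test exact, one-sided, p = 0.00794, the smallest p this design allows, n = 5 and 5). The first principal component held 25% of the variance and the second 19.2%. On an axis from the DMSO mean (0) to the rotenone mean (1), each library placed by means of the others, DMSO replicates 1, 3, 4 and 5 lay at 0.0765, 0.195, 0.343 and −0.126. The rotenone libraries lay between 0.616 and 0.941. DMSO replicate 2 lay at 0.591, nearer to the rotenone libraries than any other control.

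**Figure D1:**
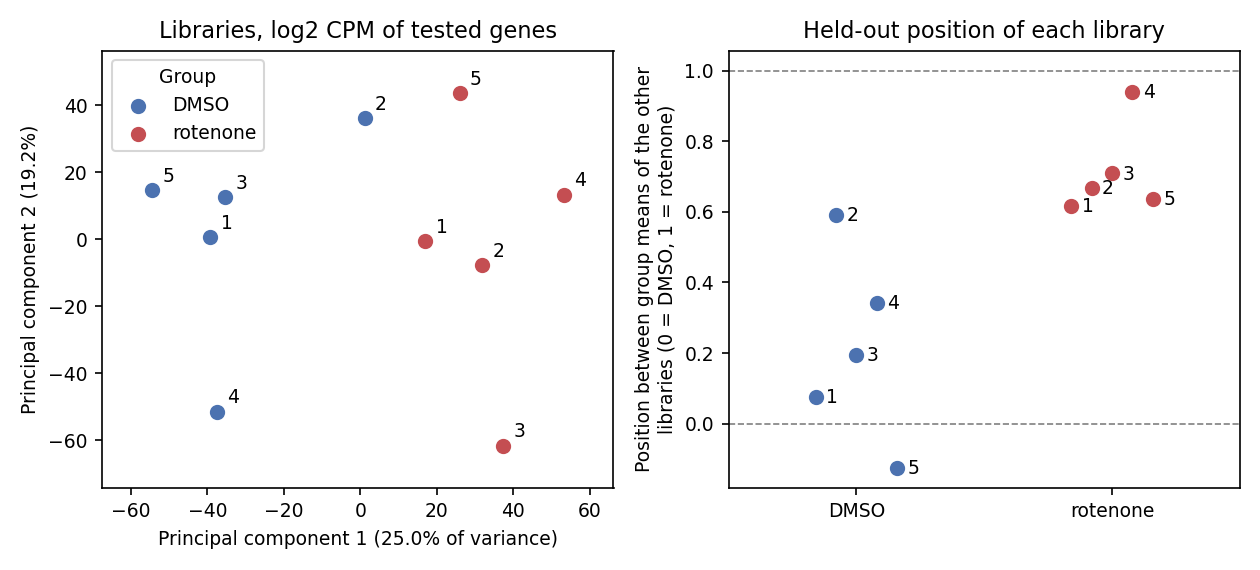
Left, each library on the first 2 principal components of log2 CPM (percent of variance on the axes), numbered by replicate; right, the position of each library between the group means of the other libraries, without unit, with dashed lines at the DMSO mean (0) and the rotenone mean (1). DMSO replicate 2 lies at 0.591 and the 5 rotenone libraries lie between 0.616 and 0.941.

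In rotenone livers 50 genes were higher and 25 lower than in DMSO livers (edgeR, adjusted p under 0.05). The higher genes differed by a median of 2.20-fold (1.48 to 10.9) and the lower genes by 2.35-fold (1.59 to 11). At least a 2-fold difference was found for 35 higher and 20 lower genes, and at least 4-fold for 6 and 4. The called genes were of moderate abundance, with a median of 21.3 CPM for those higher and 24.1 CPM for those lower, against 9.07 CPM over all tested genes. In all 75 of them every rotenone library lay on 1 side of every DMSO library. By a strict rule, 0 genes had 10 or more counts in all 5 libraries of a group and 0 counts in the other group. A few stray reads are enough to fail this rule, so it does not exclude genes nearly switched on or off.

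The files do not pair gene IDs with names, so 4 genes are given by ID. Nfu_g_1_007904 rose from 6.37 ± 1.62 CPM in DMSO to 19.5 ± 1.69 CPM in rotenone livers (mean ± SD, n = 5 each), a log2 fold change of 1.61 (SE 0.17, edgeR adjusted p = 0.0179). Nfu_g_1_010322 rose from 2.59 ± 0.756 to 11.5 ± 2.85 CPM, a log2 fold change of 2.15 (SE 0.25, edgeR adjusted p = 0.0213). Nfu_g_1_018493 fell from 2.39 ± 1.18 to 0.364 ± 0.116 CPM, a log2 fold change of −2.71 (SE 0.38, edgeR adjusted p = 0.0325). Nfu_g_1_006682 fell from 1.75 ± 0.332 to 0.396 ± 0.165 CPM, a log2 fold change of −2.13 (SE 0.31, edgeR adjusted p = 0.0325). Their lengths were 1367, 2054, 4826 and 5938 bp, and their positions in the genome are not given in the sources used here. Each kept its direction in every setting tried, which the choice by lowest p in the same libraries made likely. The adjusted p of all 4 rose above 0.05 without DMSO replicate 5 and without rotenone replicate 4 (edgeR, 0.0615 to 0.112 over both), so no call was kept there. It also rose above 0.05 without DMSO replicate 1 for Nfu_g_1_010322 (edgeR, 0.0543) and Nfu_g_1_006682 (0.0770). For both lower genes, Nfu_g_1_018493 and Nfu_g_1_006682, the edgeR adjusted p was 0.0653 without DMSO replicate 3, 0.0625 without rotenone replicate 2, and 0.0600 and 0.0605 without rotenone replicate 5. For Nfu_g_1_006682 it was 0.0592 without rotenone replicate 1. With the profile of a block of co-varying genes as a covariate it was 0.0543 for both lower genes (edgeR). On log2(RPKM + 1), deposited or with own totals, no call was kept for any of the 4 (limma adjusted p from 0.0502 to 0.0933). On that scale, which understates changes of low genes, the deposited RPKM gave log2 differences of −0.50 for Nfu_g_1_018493 and −0.33 for Nfu_g_1_006682. On log2(RPKM + 0.1) of the deposited values, Nfu_g_1_018493 alone kept its call (limma adjusted p = 0.0323), while with own totals all 4 genes kept theirs (limma adjusted p from 0.0340 to 0.0373).

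**Figure D2:**
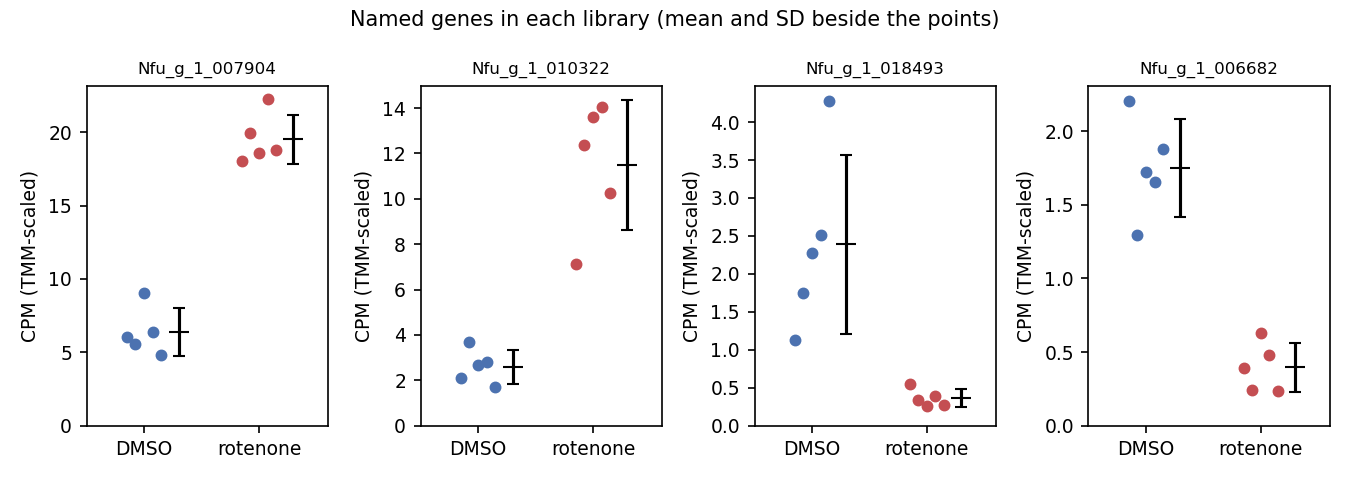
CPM (TMM-scaled) of the 4 named genes in each library, with 5 points per group; the black mark and bar beside the points are the mean and SD. The DMSO and rotenone points do not overlap in any of the 4 panels, with means of 6.37 and 19.5 CPM in the first.

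The number of called genes depended on single libraries. With a library left out, edgeR called 3 genes without DMSO replicate 1, 927 without DMSO replicate 2, 6 without DMSO replicate 3 and 99 without DMSO replicate 4. It called 18 without rotenone replicate 1, 4 without rotenone replicate 2, 41 without rotenone replicate 3 and 17 without rotenone replicate 5. Without DMSO replicate 5 or rotenone replicate 4 edgeR called 0, while 2736 and 2952 genes had an unadjusted p under 0.05. All 75 genes kept their direction and an unadjusted p under 0.05 in each of these fits. As they were chosen from the same libraries and separated the groups fully, this was close to assured and is no separate support. DESeq2 on all libraries called 813 genes higher and 743 lower, the 75 among them. With library size as the only scaling, edgeR called 10 higher and 21 lower, and the median log2 fold change of all genes moved to −0.20 from 0.00. Directions here are relative to TMM.

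**Figure D3:**
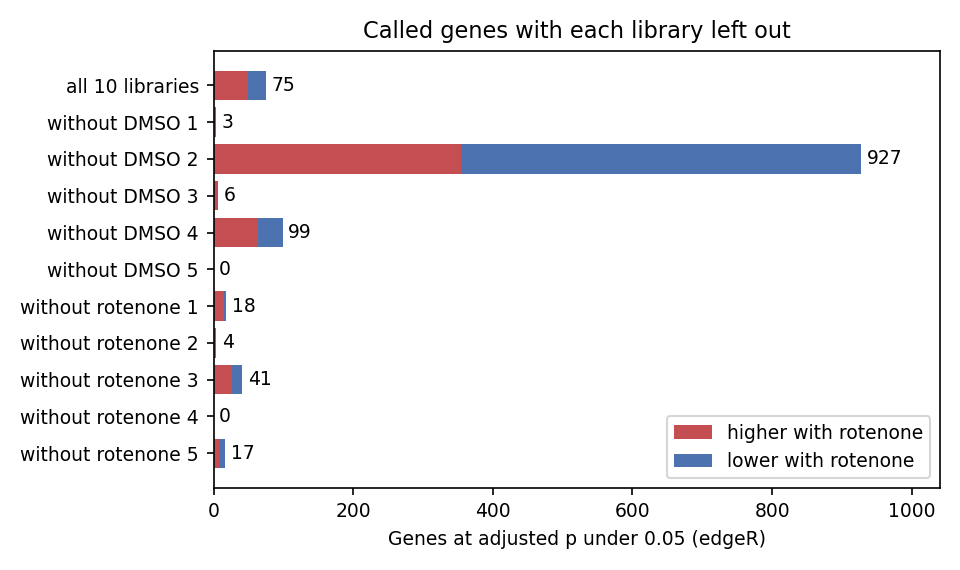
Number of genes called by edgeR (adjusted p under 0.05) with all 10 libraries and with each library left out, split into genes higher (red) and lower (blue) with rotenone. The total is 75 with all libraries, 927 without DMSO replicate 2 and 0 without DMSO replicate 5 or rotenone replicate 4.

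Below this threshold, differences were spread over many more genes and went both ways. An unadjusted p under 0.05 (edgeR) was found for 3777 genes, 22.3% of those tested, where 846 would be expected by chance, and 1886 of them were higher and 1891 lower. The groups did not overlap for 818 genes, 522 higher and 296 lower, where chance gives 0.794% of genes, or 134. That count was 2031 without DMSO replicate 2, 1604 without DMSO replicate 4, 1255 without rotenone replicate 1 and 1353 without rotenone replicate 3. With a library left out chance alone gives more genes without overlap, 1.59%. The figures of 846 and 134 are means and carry no spread. Of 100 splits of the libraries, the real one included, 2 gave at least 3777 genes at an unadjusted p under 0.05. As many as 818 genes without overlap were also found in 2. The highest counts in another split were 3948 and 1213, so chance is not excluded.

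No class of genes by abundance or length passed the test of a shift of its median. The 50 most abundant genes had a median log2 difference of 0.37, with 12 of them higher and 1 lower at an unadjusted p under 0.05 and 1 called (permutation test exact, two-sided, p = 0.0794, adjusted by Benjamini-Hochberg over 8 classes 0.571, n = 5 and 5). From the lowest to the highest quartile of abundance, 2, 12, 15 and 21 genes were called higher and 3, 4, 6 and 12 lower. Across genes, which are not independent replicates, Spearman's correlation of the log2 fold change was 0.0029 with length and 0.040 with abundance.

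Some of the most abundant liver transcripts varied strongly between libraries. Of the 50 most abundant genes, 8 differed at least 10-fold between their lowest and highest library. For 7 of these the lowest library was DMSO replicate 4, and without it 1 gene differed that much. Within a group, 2 of the 8 spanned 10-fold in DMSO and 1 in rotenone. The gene ranking 6 by abundance spanned 346 to 32867 CPM, both ends in rotenone libraries. Among the 50 most abundant genes, a cluster of 10 picked for its high variance gave a mean profile that spanned 10.4-fold (4.13-fold without DMSO replicate 4). A block of 46 genes was then picked for a correlation above 0.95 with this profile, so that they varied together follows from the choice. Of the block genes, 9 were among the 50 most abundant, and mean levels, taken on log2 CPM, ran from 0.721 to 7713 CPM. The block took 4.05, 7.17, 5.92, 1.35 and 3.44% of counts in DMSO replicates 1 to 5 and 3.55, 3.15, 3.83, 9.60 and 11% in rotenone replicates 1 to 5. The group means were 4.38 ± 2.25% and 6.22 ± 3.75% (permutation test exact, two-sided, p = 0.389, n = 5 each). edgeR called 0 block genes, the smallest adjusted p being 0.270, but it called only 75 of the 16922 tested genes. Genes picked to follow a profile that varies within both groups are also unlikely to be called, so this count decides nothing.

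**Figure D4:**
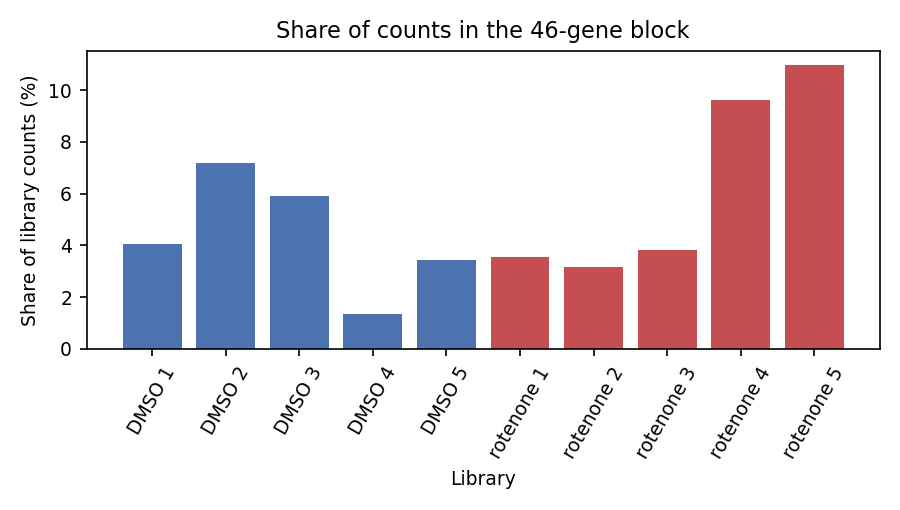
Percent of each library's counts in the block of 46 genes that varied together, 1 bar per library, DMSO in blue and rotenone in red. The share runs from 1.35% in DMSO replicate 4 to 11% in rotenone replicate 5.

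With all libraries, none of the library measures passed the test of a difference between rotenone and DMSO. Detected genes numbered 20657 ± 148 in DMSO and 20440 ± 198 in rotenone (permutation test exact, two-sided, p = 0.0873, n = 5 each), and p was 0.238 after thinning to equal depth. The 50 most abundant genes took 34.2 ± 4.88% and 36.6 ± 5.45% of counts (p = 0.492 by the same exact test, n = 5). After adjustment over 6 measures the smallest p was 0.357. Before adjustment, p for detected genes was 0.0476 without DMSO replicate 4 and 0.0317 without rotenone replicate 3, and p for the TMM factor was 0.0159 without DMSO replicate 2 (exact permutation, two-sided, 4 against 5 libraries). The distance of a library to its group mean was 0.464 ± 0.0884 in DMSO and 0.520 ± 0.0587 in rotenone (root mean square log2 CPM; permutation test exact, two-sided, p = 0.302, n = 5 each).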

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

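The tests of a single source and of a wrong label were chosen only after the result was seen, as were thinning, length correction and both covariates as settings.

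Rotenone replicate 4 stood apart from the other rotenone libraries on the held-out axis, at 0.941, by Dixon's ratio (0.712 against a critical value of 0.71). In all 32 groups of values were checked, and chance marks about 1 in 20 groups, so 1 such value is within what chance gives.

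For the genes called between rotenone and DMSO, depth and length are argued against as whole causes, since 73 of the 75 genes were still called with all libraries thinned to 1 total and 72 with a length trend removed. With the share of the 50 most abundant genes as a covariate the median ratio of new to old log2 fold change was 0.989 (interquartile range 0.953 to 1.01), and with the block profile it was 0.968 (0.923 to 1.01), but edgeR then called 45 and 16 genes, 37 and 14 of the 75 among them, with 1 residual degree of freedom fewer, and how much of the loss that explains was not tested. Of 100 splits of the libraries, the real one included, 3 called as many genes (75 in the real split, 901 in the highest other). As many genes with an unadjusted p under 0.05 were found in 2 splits (3777, highest other 3948). As many genes without overlap were also found in 2 (818, highest other 1213). Such counts were rare among the splits run, but the real split was the highest on none of them. Some possible splits were not run, so chance is not excluded for these counts. The split with 901 exchanges DMSO replicate 2 with rotenone replicate 3, and one with 234 exchanges it with rotenone replicate 1. Exchanging DMSO replicate 2 with rotenone replicate 2 or 5 gave 0 calls by edgeR (2997 and 2301 genes at an unadjusted p under 0.05). Its exchange with rotenone replicate 4 was not run. The number of calls also moved strongly with single libraries, so whether the samples hold a structure besides the labelled groups was not settled. An effect of rotenone on these genes stays open as a hypothesis, beside chance, such a structure and the wrong label or swap of DMSO replicate 2 weighed below.

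For the block of genes that varied between libraries, transcript length is argued against, as other genes of the block's lengths had a median slope of −0.0187 on the block profile. Whether rotenone contributed is open: the block's share gave p = 0.389 (exact permutation, two-sided, n = 5), and the bound set beforehand, an interval for the log2 difference in profile ending below its range over all libraries (2.02 against 3.38), would be met almost whenever libraries vary within groups. On the profile the libraries labelled DMSO alone spanned 6.65-fold, a range that rests on DMSO replicates 2 and 4. It was 3.92-fold without DMSO replicate 2, whose label is weighed next, and 2.60-fold without DMSO replicate 4. The libraries labelled rotenone alone spanned 4.13-fold, and with a library left out the lowest span was 3.79-fold, without rotenone replicate 2. A single source of RNA mixed into the libraries in varying amounts may contribute, but the 37 genes tested were chosen by a correlation above 0.95 with the profile, so their median slope of 0.956 (interquartile range 0.809 to 1.01) decides nothing. Without gene names no tissue or cell type could be tested as that source.

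For the place of DMSO replicate 2 between the groups, the block is argued against, as taking out the block trend moved its position from 0.591 to 0.615, away from the other DMSO libraries. The same correction put rotenone replicates 1, 2 and 5 at 0.510, 0.559 and 0.583, below it. A wrong label cannot be told apart from a control that varied: its mean distance to the rotenone libraries exceeded that to the other DMSO libraries by 0.0118, against a pooled SD of 0.107. A swap between the groups is open too, since rotenone replicate 1 lay about as far from the DMSO libraries (0.789) as from the other rotenone libraries (0.779). Exchanging it with DMSO replicate 2 gave 234 calls, but fewer genes at an unadjusted p under 0.05 (3538) and without overlap (784) than the real split (3777 and 818). The exchange with rotenone replicate 3 gave 901 calls and more of both (3948 and 1213). That library lay farther from the DMSO libraries (0.960) than from its own group (0.896), at 0.709 on the axis. No biological explanation was tested for this library.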

How the results depend on the processing

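The RPKM with own totals, thinning, length removal, covariates and DESeq2 without DMSO replicate 2 were chosen after the result was seen, as were all alternatives for the unadjusted count and the count of genes without overlap itself. So was the use of only the genes outside the block and its correlates for the share of variance and the spread. The main counts were 50 genes higher and 25 lower. They became 10 and 21 with library size only, 813 and 743 with DESeq2, 1005 and 862 with voom and sample quality weights, and 486 and 442 at an adjusted p threshold of 0.1. On deposited RPKM limma called 0 and 0 with a pseudocount of 1 (3536 genes at an unadjusted p under 0.05) and 1 and 10 with 0.1. With own totals these were 0 and 0 (3455 genes at an unadjusted p under 0.05) and 4 and 14. They were 12 and 4 with the block covariate, 29 and 16 with the top-50 covariate, and 1198 and 1317 with DESeq2 without DMSO replicate 2. With each library left out in turn they ran from 0 to 355 and from 0 to 572. Fewer samples entered those fits, and the cause of the other changes was not tested. The 818 genes without overlap became 472 with library size only and ran from 901 to 2031 with a library left out, where chance gives 1.59% of genes and not 0.794%.

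The share of variance between the groups and the difference in spread stayed on their side of the threshold in the 15 alternatives run for each, although the difference in spread of 0.0561 was 0.00925 without rotenone replicate 3 (exact permutation p = 0.881), 0.113 without DMSO replicate 4 (p = 0.0556), 0.0949 without DMSO replicate 2 (p = 0.0873), 0.430 over the 500 most variable genes (p = 0.0794) and 0.0215 on deposited RPKM (p = 0.690) or 0.0294 with own totals (p = 0.452), and the count at an unadjusted p under 0.05 stayed within 1.5 times of 3777 in all 28. The 4 named genes kept their direction in every setting, which their choice by lowest p in the same libraries made likely. Gene list tests and their alternatives were not run, as no ID matched a gene name. No paired analysis was possible because the replicate numbers only name the libraries. In splits with new groups of 3 and 2 libraries from each old group, DESeq2 called a median of 11 genes over 20 of them (2 to 201), and edgeR a median of 0 over 82 (highest 11). At this depth and spread, edgeR recovered 0% of simulated 1.5-fold changes when 200 genes were changed. The data differ from that setting, since 3777 genes had an unadjusted p under 0.05, and 20 of the 75 called genes differed by less than 2-fold (the lowest 1.48-fold). Some small changes were therefore called, and how many were missed is not known.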

Other observations

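Rotenone replicate 3 held 77 genes at least 8-fold above every other library, where each other library held between 0 and 2. Their median was 72.4 CPM in that library and 0.885 CPM over the others, and they took 2.88% of its counts against at most 0.130% elsewhere. These genes were singled out after their values were seen, and no explanation was tested.

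Across the 10 libraries the block's share of counts went with a lower TMM factor (Pearson's r = −0.795, permutation test, two-sided, p = 0.00783, Benjamini-Hochberg over 2 relations 0.0157). Spearman's rho was −0.527 (permutation test, two-sided, p = 0.123, adjusted 0.123). Both values come from the same counts, and more counts in a few abundant genes can by itself lower the TMM factor. The permutation test treats them as unrelated, so its p decides little. Without the 2 libraries farthest from the median share, rotenone replicates 4 and 5, Pearson's r was −0.403, so the size of r rests largely on those libraries. As both are rotenone libraries, share and group are partly mixed in r. Leaving out extremes narrows the range of shares, which can itself lower r. A correlation within a group is not given, as each holds only 5 libraries.

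The shift in the deposited RPKM differed between groups by −0.28 to 0.00 log2, depending on the gene's place in the cycle of divisors, so fold changes taken from that table carry this offset.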
